A study of Pseudomonas aeruginosa PAO1 with 6 samples.

How the data were processed

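RNA was measured in 6 libraries of Pseudomonas aeruginosa PAO1, 3 from flasks given rosmarinic acid and 3 from flasks given DMSO, as the sample titles state. Per the labels' protocols the flasks were filled from 3 independent cultures, ribosomal RNA was removed with a RiboZero kit, libraries were made with the TruSeq Stranded Total RNA kit and sequencing was done on an Illumina NextSeq instrument. Which flask came from which culture is not stated, so a shared replicate number was not taken as a pair, and p-values measure the spread between flasks that partly share a starting culture. The submitters' processing notes name FastQC and Bowtie2 without versions. The counting tool, the genome build, the annotation and the use of strand in counting are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart.

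Each library had a table with the average coverage, the number of reads and the RPKM of 5647 features. The deposited average coverage is a signal per base over each feature, per the file headers. The deposited read numbers, which were whole, were treated as estimated counts. Coverage times feature length divided by the read number had a per-library median, over features with many reads, of 74 or 75 bases. It was 75 bases in rosmarinic acid replicate 2 and DMSO replicate 1 and 74 bases in the other libraries. This ratio cannot show which of coverage and read number was derived from the other. The RPKM column, per the file headers, held reads scaled by length and library, and as deposited it was rounded to whole numbers, so it was handled as a score on the RPKM scale. From the values, its divisor in each library was larger than the sum of that library's read numbers, and the source of that divisor is not stated. A further table of the whole series held the authors' own comparison for 280 genes with an adjusted p-value under 0.05, per the file headers: a mean signal, a log2 fold change, its standard error as a score, a p-value, an adjusted p-value and a normalised signal per library. The authors' column names are those that DESeq2 writes, but no tool is named, and genes outside that threshold were not analysed from it. For 279 of its 280 genes the deposited signal was the read number divided by 1 constant per library to within a relative 1e-09. The exception was lptF, a name shared by a pair of features, whose entry carried one locus tag and the values of the other feature (largest relative difference 3.55e-15).

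Totals of the read numbers ran from 15871976 (rosmarinic acid replicate 1) to 26532893 (DMSO replicate 3). The lowest count of any feature was between 3 and 8 reads per library. Of the 5647 features, 5558 matched a gene of the PAO1 assembly ASM676v1 by start and end, 28 by locus tag and 5 by symbol, 46 kept the name in the files and 10 had no match. That gene table was used for names, locus tags and order, and all coordinates are those of the files. The pilus gene pilC had no matching feature. Libraries of one group were compared with a chi-square per degree of freedom of their counts, which was lowest at 29.4 (DMSO replicates 2 and 3), so no library was a copy of another. Correlations of log2 CPM were 0.986 to 0.990 within rosmarinic acid, 0.991 to 0.995 within DMSO and 0.972 to 0.985 between the groups.

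The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited read numbers of all 6 libraries with the group as the only term. TMM factors were 0.968 to 1.047, and filterByExpr with a minimum count of 10 left 5643 features. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 14.2%. Assembled from general knowledge of PAO1, 34 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 and again with an estimated correlation, and adjusted p-values of camera are over the 34 lists. The groups, the test, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took, among called genes with a mean of at least 10 CPM and groups that did not overlap, the 10 highest and 10 lowest fold changes. It also took the 3 called members with the smallest p of each list with at least 3 called, the regulators and synthases lasR, lasI, rhlR, rhlI and mvfR, the 2 members with the smallest p of other lists called by camera, and the 3 highest and 3 lowest fold changes of the authors' deposited table. Percentages of ribosomal RNA were compared with an exact two-sided permutation test.

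The design had assumed read counts. Whether the deposited read numbers were counted directly or derived from coverage is not known, and the same test was kept. Tested on simulated counts for 5643 genes with 200 genes changed, the edgeR test of 3 against 3 libraries recovered 99.4% of genes changed 3-fold and 49.6% of those changed 1.5-fold over 10 draws, and 5.7% of its calls were unchanged genes. In a single draw DESeq2 recovered 99% and 63%, with 14.7% of its calls unchanged genes. In that draw edgeR recovered 99% and 42%, with 9.6% of its calls unchanged genes. Of 20 simulated unchanged lists camera called 0 under either correlation. The simulated genes varied independently of each other, so this cannot show how often camera calls unchanged lists whose genes vary together.

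Alternatives were DESeq2 (version 1.42.0), its size factors, upper-quartile factors or library size only in edgeR, no filter, a minimum mean of 50 reads, the replicate number as a block, limma on log2 of the rounded RPKM plus 1, 0.1 or 5, limma-voom, leaving out ribosomal and transfer RNA genes, leaving out each library in turn, and for lists fry, other scalings and other members. Added after seeing the data were DESeq2 with its older shrunken fold changes, thinning each library to the smallest total, and counts of called list members without each library. Tables were joined with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.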

Results

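The series measured the transcriptome of Pseudomonas aeruginosa PAO1, a widely used laboratory strain of this opportunistic pathogen, after growth with rosmarinic acid, a phenolic ester made by plants such as rosemary and basil. Per the labels, 3 independent cultures in rich medium were grown to early exponential phase and divided over 6 flasks. Rosmarinic acid at 100 µM, dissolved in dimethyl sulfoxide (DMSO), was added to 3 flasks and DMSO alone to the other 3, and RNA was taken 2 hours later. The growth phase tag of the labels reads late exponential, without saying whether it refers to the time of treatment or of RNA extraction. The treatment tag of the labels gives the dose in mM, whereas the sample titles, the protocol and the design text give 100 µM. Ribosomal RNA was depleted before sequencing. The deposited files listed 5647 features per library, and their read numbers summed to 15871976, 17462571 and 20743366 in rosmarinic acid replicates 1 to 3 and to 23988028, 16196561 and 26532893 in DMSO replicates 1 to 3. At these totals a value of 1 CPM (count scaled to library size) stood for about 15.9 reads in the shallowest library and 26.5 reads in the deepest, and the lowest count of any feature was between 3 and 8 reads per library. Expression is given below as TMM-scaled CPM, mean ± SD over n = 3 libraries per group, and fold changes are rosmarinic acid over DMSO. The standard error (SE) given with an edgeR log2 fold change is its absolute value divided by the square root of the test's F statistic. This SE thus restates the test result and is not a separate estimate of spread.

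The comparison asked which transcripts differ in PAO1 cells that met rosmarinic acid. From the literature, this compound binds RhlR, a regulator of quorum sensing, the system by which bacteria regulate genes through secreted signal molecules. Genes of quorum sensing and of the products it controls made up most of the rise: 83 of the 131 risen genes were on a list of 154 quorum-sensing induced genes fixed beforehand. Among called genes averaging at least 10 CPM, the highest fold changes were at PA3328, PA3330, fabH2 and PA3334 of one gene cluster, at ambD and ambE, which take part in making the toxin L-2-amino-4-methoxy-trans-3-butenoic acid (AMB), at the phenazine gene phzB1, at lasI and its neighbour rsaL, and at the elastase gene lasB. PA3328 rose 17.5-fold, from 2.08 ± 0.470 to 36.9 ± 4.03 CPM, and ambD rose 16.5-fold, from 2.75 ± 0.536 to 46.1 ± 3.41 CPM. Few genes fell, and the lowest fold change was that of mmsA, 2.06-fold lower. In all, 144 of 5643 tested features passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 131 rose and 13 fell. A change of 2-fold or more was met by 87 risen genes and 1 fallen gene. Each of the 144 had all 3 rosmarinic acid libraries on one side of all 3 DMSO libraries, an arrangement that chance alone gives 10% of genes and that held for 1155 of all tested features. The median log2 fold change of all tested features was 0.0055. Ribosomal RNA made up 2.25 ± 0.542% of reads with rosmarinic acid and 1.22 ± 0.416% with DMSO (n = 3 each, exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows). DESeq2 called 245 genes, 188 risen and 57 fallen, and leaving out rosmarinic acid replicate 3 gave 284 genes, 165 risen and 119 fallen. With limma on log2 of the rounded RPKM plus 1, 92 genes were called, and the log2 fold changes of PA3328, ambD and PA3330 ran from 2.19, 2.48 and 2.16 with 5 added to 6.23, 5.30 and 4.92 with 0.1 added, where these 3 genes were not called (limma, Benjamini-Hochberg adjusted p = 0.107, 0.142 and 0.16).

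Among the regulators and signal synthases of quorum sensing, lasI and rsaL rose, while their neighbour lasR, for a regulator that binds the lasI product's signal, did not pass the test. The signal synthase gene lasI (bases 1559254 to 1559859), whose product makes the long-chain homoserine lactone signal, rose 10.04-fold from 49.3 ± 4.51 to 496 ± 157 CPM (log2 3.33, SE 0.22; edgeR, Benjamini-Hochberg adjusted p = 3.02e-05). The repressor gene rsaL (bases 1558880 to 1559122), which lies between lasR and lasI, rose 12.2-fold from 33.5 ± 4.04 to 410 ± 96.1 CPM. For lasR the means were 327 ± 46.8 CPM with rosmarinic acid and 362 ± 24.0 CPM with DMSO (log2 -0.15, SE 0.12; edgeR, Benjamini-Hochberg adjusted p = 0.622). The synthase gene rhlI, whose product makes the short-chain homoserine lactone, rose 2.60-fold from 19.5 ± 0.865 to 50.7 ± 5.85 CPM. Its regulator gene rhlR had 141 ± 34.7 CPM with rosmarinic acid and 98.4 ± 2.55 CPM with DMSO (log2 0.52, SE 0.16), which did not pass edgeR's test (Benjamini-Hochberg adjusted p = 0.178) and passed that of DESeq2 (adjusted p = 0.0427). The regulator genes vqsR and mvfR (also pqsR, the alkylquinolone receptor) rose 5.37-fold and 1.60-fold. Of the 12 regulators and synthases measured, 5 rose, 0 fell and 7 were not called, and 6 rose when p was adjusted over the list alone. The camera test called the list (median log2 fold change 0.46, Benjamini-Hochberg adjusted p = 1.14e-08), but not with the correlation between genes taken from the data (adjusted p = 0.22 with an estimated correlation).

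**Figure D1:**
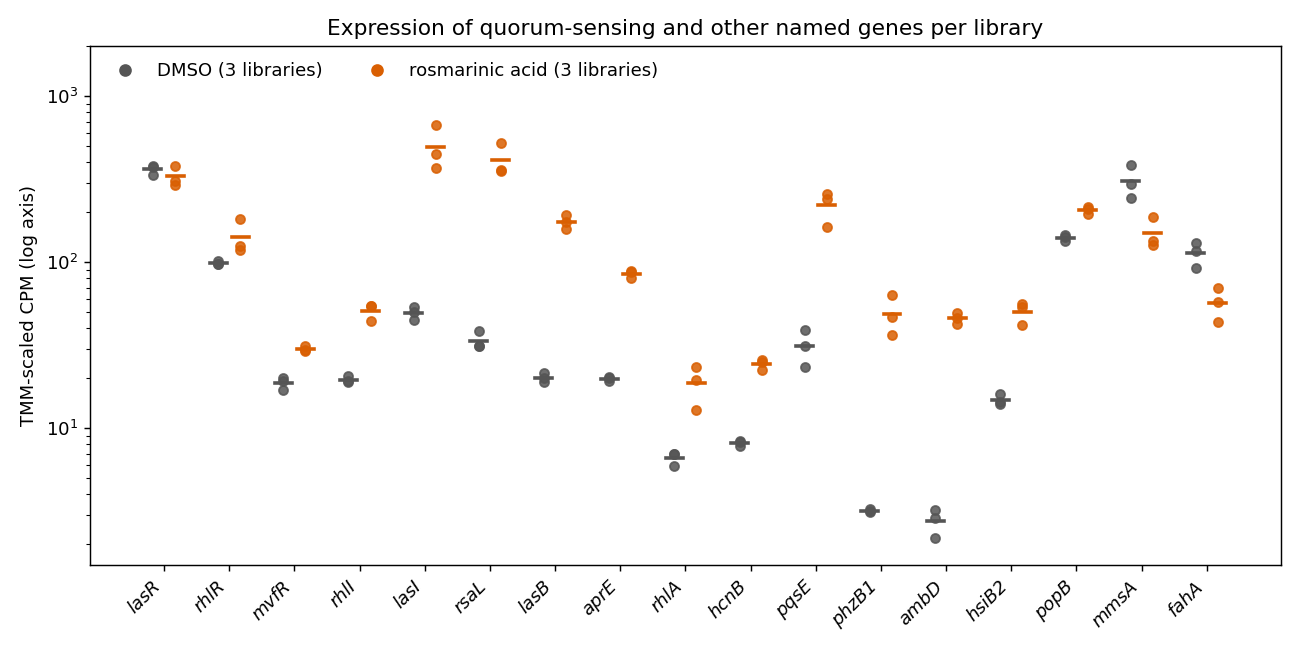
TMM-scaled CPM of 17 genes on a log axis, with a point for each of 3 DMSO libraries (grey) and 3 rosmarinic acid libraries (orange) and bars at the group means. The groups overlap at lasR, where the means are 362 and 327 CPM, and lie apart at the other 16 genes, for example lasB at 20.1 and 174 CPM.

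Most of the listed secreted proteases and other exoenzymes rose. The elastase gene lasB (bases 4168987 to 4170483) rose 8.66-fold from 20.1 ± 1.23 to 174 ± 16.8 CPM (log2 3.11, SE 0.11; edgeR, Benjamini-Hochberg adjusted p = 2.07e-06), and aprE and aprD, which encode parts of the alkaline protease exporter, rose 4.29-fold and 4.04-fold. Of 19 measured members 12 rose, by 1.43 to 8.66-fold, 0 fell and 7 were not called, and 14 rose adjusted over the list alone. The list was called by camera with Benjamini-Hochberg adjustment (adjusted p = 4.04e-20) and also when the correlation was estimated (adjusted p = 0.0381 with an estimated correlation). All 3 genes for hydrogen cyanide synthesis rose, here and adjusted over the list alone: hcnA 6.12-fold to 6.34 ± 0.135 CPM, hcnB 2.99-fold to 24.3 ± 1.69 CPM and hcnC 3.46-fold to 77.7 ± 11.2 CPM. The camera test called them with Benjamini-Hochberg adjustment (adjusted p = 1.93e-08, and adjusted p = 0.0381 with an estimated correlation).

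The rhamnolipid genes rhlA and rhlB, which encode the first steps of making this surfactant, and PA1131, next to rhlC, rose from low levels. The rise of rhlA was 2.81-fold, from 6.62 ± 0.607 to 18.5 ± 5.24 CPM (log2 1.49, SE 0.21; edgeR, Benjamini-Hochberg adjusted p = 0.00474), that of rhlB 1.78-fold and that of PA1131 2.06-fold. These were 3 of the 5 measured list members, with 0 fallen and 2 not called, and 3 rose adjusted over the list alone, but 1 was called when DMSO replicate 3 was left out. The list passed camera with Benjamini-Hochberg adjustment (adjusted p = 0.000374) and not when the correlation was estimated (adjusted p = 0.11 with an estimated correlation). All 9 genes of alkylquinolone synthesis, which yields the Pseudomonas quinolone signal, rose by 1.83 to 7.06-fold, and 9 rose adjusted over the list alone. The largest of these rises was that of pqsE, from 31.1 ± 7.71 to 220 ± 50.6 CPM, while phnA rose 4.92-fold and pqsH 4.18-fold. Their camera result with Benjamini-Hochberg adjustment was an adjusted p = 4.04e-20, and adjusted p = 0.0775 with an estimated correlation.

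Phenazines, redox-active pigments that include pyocyanin, are made from a pair of nearly identical operons. Of 21 measured genes for their synthesis and export 11 rose, by 1.37 to 15.3-fold, 0 fell and 10 were not called, and 16 rose adjusted over the list alone. Without DMSO replicate 1, or without DMSO replicate 2, 7 were called. The first genes of the first operon rose most: phzB1 15.3-fold from 3.18 ± 0.0670 to 48.7 ± 13.5 CPM, and phzA1 10.03-fold from 0.584 ± 0.210 to 5.94 ± 1.74 CPM. A 3.46-fold rise was found for phzD1, but the deposited counts of phzD, phzE and phzF were identical for both operon copies in every library, so which copy the reads came from is not known, and 3 of the 11 risen genes repeat the counts of another, in the tests of this list as well. The camera test called the list with Benjamini-Hochberg adjustment (adjusted p = 2.06e-17), and the call was lost when the correlation was estimated (adjusted p = 0.0581 with an estimated correlation).

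The broad list of quorum-sensing induced genes, which shares members with the groups above, moved as a whole. Of its 154 members 83 rose, by 1.37 to 17.5-fold, 0 fell and 71 were not called, and 108 rose adjusted over the list alone. The median log2 fold change was 0.85, 145 members lay above 0, and 115 had groups that did not overlap. Camera gave the list an adjusted p = 2.53e-76 with Benjamini-Hochberg adjustment over 34 lists, and adjusted p = 0.00524 with an estimated correlation. Besides ambD, the gene ambE of the AMB cluster rose 8.57-fold from 22.1 ± 0.891 to 190 ± 15.4 CPM (log2 3.10, SE 0.10; edgeR, Benjamini-Hochberg adjusted p = 2.07e-06).

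Many of the risen genes lay side by side. There were 15 runs of at least 3 adjacent risen genes, which held 85 of the 131, and 0 such runs of fallen genes. The runs from phzD1 to phzF1 and from phzD2 to phzF2 hold the same counts, so 1 run and 3 genes repeat another. Positions are those of the deposited files, whose genome build is not given in the sources used here. The longest runs were 11 genes from PA3325 to PA3335 (bases 3728240 to 3744809), which rose 2.03 to 17.5-fold, and 11 genes from hsiA2 to lip2 (bases 1803626 to 1816858), which rose 1.87 to 3.40-fold. Within the first of these, PA3330 rose 12.4-fold, fabH2 13.1-fold and PA3334 8.97-fold, from DMSO means of 2.55 ± 0.542, 4.78 ± 0.882 and 2.44 ± 0.410 CPM. A run of 10 genes from PA4126 to PA4135 (bases 4614024 to 4625003) rose 1.61 to 7.82-fold. The alkylquinolone run from pqsA to mvfR held 8 genes (bases 1078462 to 1087095), the alkaline protease run from aprX to PA1251 held 7 (bases 1349416 to 1359350), and the run from chiC to ambB held 6 (bases 2530389 to 2544946). The 5 genes from PA3904 to PA3908 (bases 4373938 to 4376731) rose 4.77 to 10.04-fold. The 6 genes from PA0492 to PA0497 (bases 551911 to 557276), none of them on a fixed list, rose 1.84 to 2.15-fold.

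**Figure D2:**
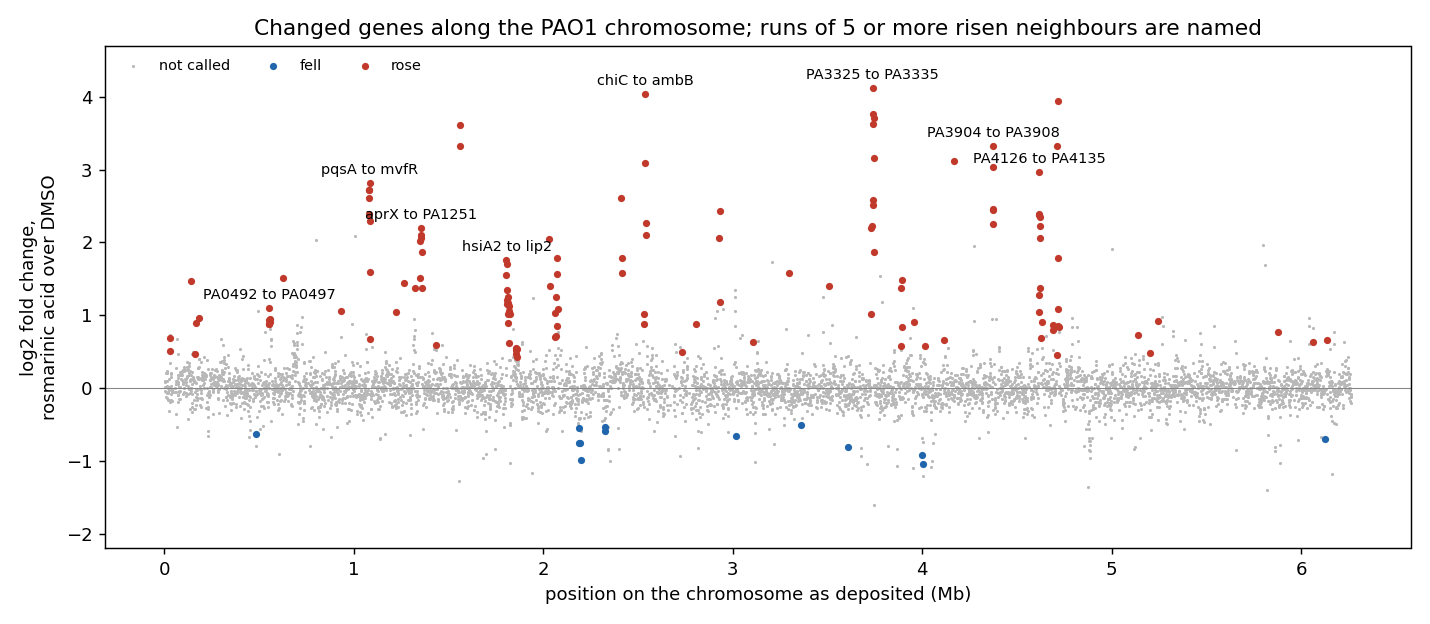
Log2 fold change, rosmarinic acid over DMSO, of each tested feature against its position in megabases as deposited, with risen genes in red, fallen genes in blue and all others in grey. The named runs of at least 5 adjacent risen genes reach log2 4.13 in the run from PA3325 to PA3335, whereas the lowest of the 13 fallen genes lies at log2 -1.04.

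Of the secretion machines that deliver proteins into other cells or the medium, the H2 type VI system, a needle that injects effectors into neighbouring cells, rose nearly throughout. Of its 16 measured genes 14 rose, by 1.54 to 3.40-fold, 0 fell and 2 were not called, and all 16 rose adjusted over the list alone. The sheath gene hsiB2 rose 3.40-fold from 14.8 ± 1.16 to 50.2 ± 7.53 CPM (log2 1.76, SE 0.13; edgeR, Benjamini-Hochberg adjusted p = 6.19e-05), hsiH2 rose 2.56-fold and sfa2 2.39-fold. Camera called the H2 list with Benjamini-Hochberg adjustment (adjusted p = 4.28e-26, and adjusted p = 0.00524 with an estimated correlation). Of these 16 genes, those on the broad quorum-sensing list are counted there as well. The H1 and H3 type VI systems had 0 called genes among 18 and 15 by edgeR, whether adjusted over all genes or adjusted over the list alone. For H1 the median log2 fold change was 0.15 (camera, Benjamini-Hochberg adjusted p = 0.0398, and adjusted p = 0.827 with an estimated correlation), and its members with the smallest p, tssG1 and icmF1, had log2 fold changes of 0.25 and 0.24. With each library left out in turn the camera adjusted p of the H1 list (Benjamini-Hochberg) ran from 0.000618 to 0.498, and the call was lost without rosmarinic acid replicate 1, rosmarinic acid replicate 2 or DMSO replicate 1. For H3 the median was -0.05 (camera, Benjamini-Hochberg adjusted p = 0.407).

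Type III secretion, the injection system for toxins into host cells, showed small rises. The translocator genes popB and popD and their chaperone gene pcrH, which are neighbours, rose 1.47, 1.38 and 1.44-fold, popB from 140 ± 5.66 to 206 ± 10.5 CPM (log2 0.56, SE 0.09; edgeR, Benjamini-Hochberg adjusted p = 0.00815). Of 39 measured genes 5 rose, 0 fell and 34 were not called, 10 rose adjusted over the list alone, and 38 had a log2 fold change above 0 with a median of 0.33. Camera called the list with Benjamini-Hochberg adjustment (adjusted p = 1.49e-11), but not when the correlation was estimated (adjusted p = 0.0962 with an estimated correlation). The number of called members lay between 0 and 7 when each library was left out in turn, with 0 when DMSO replicate 3 was left out, 1 without rosmarinic acid replicate 1 or 2 and 2 without DMSO replicate 1 or 2. The Xcp type II system, which exports elastase, had 0 of 11 genes called by edgeR, also adjusted over the list alone, with a median log2 fold change of 0.17 (camera, Benjamini-Hochberg adjusted p = 0.142).

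Of the 13 fallen genes 12 lay outside all fixed lists. The neighbours mmsA and mmsB, whose products degrade valine (bases 4001196 to 4003601), had 149 ± 32.4 and 50.2 ± 10.5 CPM with rosmarinic acid against 306 ± 69.9 and 94.5 ± 22.2 CPM with DMSO. These values made mmsA 2.06-fold lower (log2 -1.04, SE 0.20; edgeR, Benjamini-Hochberg adjusted p = 0.0256) and mmsB 1.88-fold lower (adjusted p = 0.0493). The gene fahA, for fumarylacetoacetase of tyrosine breakdown, was 1.99-fold lower (log2 -0.99, SE 0.18). Near it on the chromosome, bdhA for 3-hydroxybutyrate dehydrogenase and PA2004 were each 1.69-fold lower. Further falls were 1.75-fold at csaA, 1.63-fold at PA5440, 1.58-fold at mvaU, which encodes a nucleoid protein, 1.55-fold at PA0434 and 1.51-fold at PA2116. The other fallen genes, named after their values were seen, were dhcB at 1.47-fold, PA2114 at 1.45-fold and PA3001 at 1.41-fold lower. Leaving out each library in turn gave between 3 and 119 fallen genes, and mmsB lost its call in 12 of 20 alternative analyses, PA5440 in 8, mmsA in 7 and fahA in 5. With the replicate number as a block, 9 of the 13 kept their call.

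The breakdown of aromatic compounds, a class to which rosmarinic acid belongs, was covered by 3 lists. On the list for tyrosine, homogentisate and hydroxyphenylacetate 2 of 17 genes rose, 1 fell and 14 were not called, and 2 rose and 3 fell adjusted over the list alone. The risen genes were hpcG, for a hydratase of hydroxyphenylacetate breakdown, 2.42-fold from 8.50 ± 0.889 to 20.5 ± 1.08 CPM, and PA4126, 2.07-fold, which both belong to the run from PA4126 to PA4135. The fallen gene was fahA, which was not called without rosmarinic acid replicate 2, DMSO replicate 1 or DMSO replicate 3, while 3 members were called as fallen without rosmarinic acid replicate 3. The list as a whole had a median log2 fold change of -0.03 (camera, Benjamini-Hochberg adjusted p = 0.68). Catechol and anthranilate breakdown had 0 of 11 genes called by edgeR (median log2 fold change 0.00964; camera, Benjamini-Hochberg adjusted p = 0.773), and protocatechuate and hydroxybenzoate breakdown 0 of 18 (median 0.11; adjusted p = 0.122), also adjusted over the list alone.

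All 8 genes of the arginine deiminase and anaerobic growth list lay below 0, with a median of -0.53, and 0 were called by edgeR, also adjusted over the list alone. Camera called the list (Benjamini-Hochberg adjusted p = 0.000438), but not when the correlation was estimated (adjusted p = 0.379 with an estimated correlation). The coproporphyrinogen oxidase gene hemN had 406 ± 181 CPM with rosmarinic acid and 790 ± 181 CPM with DMSO (log2 -0.96, SE 0.29; edgeR, Benjamini-Hochberg adjusted p = 0.186), and anr, for the regulator of this response, 84.3 ± 7.79 and 107 ± 12.3 CPM. Relative to the DMSO mean the list's median log2 ratio was -0.75 and -0.62 in rosmarinic acid replicates 1 and 2 and -0.20 in replicate 3, and it ranged from -0.45 to 0.46 over the DMSO libraries. Without rosmarinic acid replicate 3, 2 members were called as fallen. Denitrification had 0 of 28 genes called by edgeR (median -0.05; camera, Benjamini-Hochberg adjusted p = 0.164), and alternative terminal oxidases 0 of 10 (median 0.19; adjusted p = 0.715), with 0 and 1 fallen adjusted over the list alone.

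Among stress and phage-like functions, ibpA, a small heat shock chaperone, rose 2.64-fold from 220 ± 67.4 to 582 ± 192 CPM (log2 1.40, SE 0.28; edgeR, Benjamini-Hochberg adjusted p = 0.0386). It was the 1 called gene of 14 for heat shock and protein quality control, also adjusted over the list alone, and lost its call without any one library other than rosmarinic acid replicate 3. The co-chaperone gene dnaJ had a log2 fold change of 0.42 (SE 0.13), and the list a median of 0.29 (camera, Benjamini-Hochberg adjusted p = 0.0153, and adjusted p = 0.546 with an estimated correlation). That call was lost without rosmarinic acid replicate 1 or DMSO replicate 1, the adjusted p from camera reaching 0.0535 with Benjamini-Hochberg adjustment. The R- and F-type pyocins, phage-tail-like bacteriocins, had 0 of 39 genes called by edgeR over all genes, 19 risen adjusted over the list alone and 12 risen over all genes without rosmarinic acid replicate 1. Their median log2 fold change was 0.36 (camera, Benjamini-Hochberg adjusted p = 1.94e-10, and adjusted p = 0.54 with an estimated correlation), with PA0613 at 0.48 (SE 0.11) and PA0645 at 0.59 (SE 0.14), and DESeq2 called both of these genes. Relative to the DMSO mean the median log2 ratio of the pyocin list was 0.075 in rosmarinic acid replicate 1, 0.40 in replicate 2 and 0.57 in replicate 3, and it ranged from -0.039 to 0.026 over the DMSO libraries. Oxidative stress had 0 of 14 genes called by edgeR (median -0.02; camera, Benjamini-Hochberg adjusted p = 0.594) and the SOS response 0 of 8 (median -0.04; adjusted p = 0.504), also adjusted over the list alone. Stationary phase and osmotic stress had 0 of 9 called over all genes and 4 risen adjusted over the list alone (median 0.08; camera, Benjamini-Hochberg adjusted p = 0.117).

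Surface structures, iron uptake, efflux and housekeeping functions held few calls. Of 24 efflux pump genes of the RND family 1 rose, mexK at 1.58-fold, named after its value was seen, and 2 rose adjusted over the list alone (median 0.05; camera, Benjamini-Hochberg adjusted p = 0.223). The number called was 0 without rosmarinic acid replicate 2 or any one of the DMSO replicates, and 2 without rosmarinic acid replicate 3. The exopolysaccharides Pel and Psl with the adhesin Cdr had 0 of 21 genes called by edgeR, also adjusted over the list alone, and a median of 0.12 (camera, Benjamini-Hochberg adjusted p = 0.00341, and adjusted p = 0.101 with an estimated correlation), with pslJ at log2 0.40 (SE 0.10) and pslK at 0.31 (SE 0.10). Without rosmarinic acid replicate 3, pslJ passed edgeR's test (Benjamini-Hochberg adjusted p = 0.031). The other lists had 0 called genes by edgeR, whether over all genes or adjusted over the list alone, and none passed camera with Benjamini-Hochberg adjustment. For pyoverdine the median of 18 genes was -0.0145 (adjusted p = 0.641), for pyochelin that of 11 was -0.10 (adjusted p = 0.916) and for other iron uptake that of 12 was -0.06 (adjusted p = 0.594). Flagella and chemotaxis had a median of 0.09 over 46 genes (adjusted p = 0.122), type IV pili 0.00888 over 25 (adjusted p = 0.82) and alginate 0.05 over 15 (adjusted p = 0.545). The MexT regulon had a median of 0.0103 over 18 genes (adjusted p = 0.759), ribosomal proteins 0.09 over 53 (adjusted p = 0.407) and ATP synthase 0.14 over 9 (adjusted p = 0.307). For the MexT regulon, type IV pili and catechol breakdown the median lay above 0 while the mean and the direction of the camera test lay below 0. Camera called 14 of the 34 lists, 13 upward and 1 downward, and with an estimated correlation 4 of these, namely the broad quorum-sensing list, exoenzymes, hydrogen cyanide and the H2 type VI system.

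**Figure D3:**
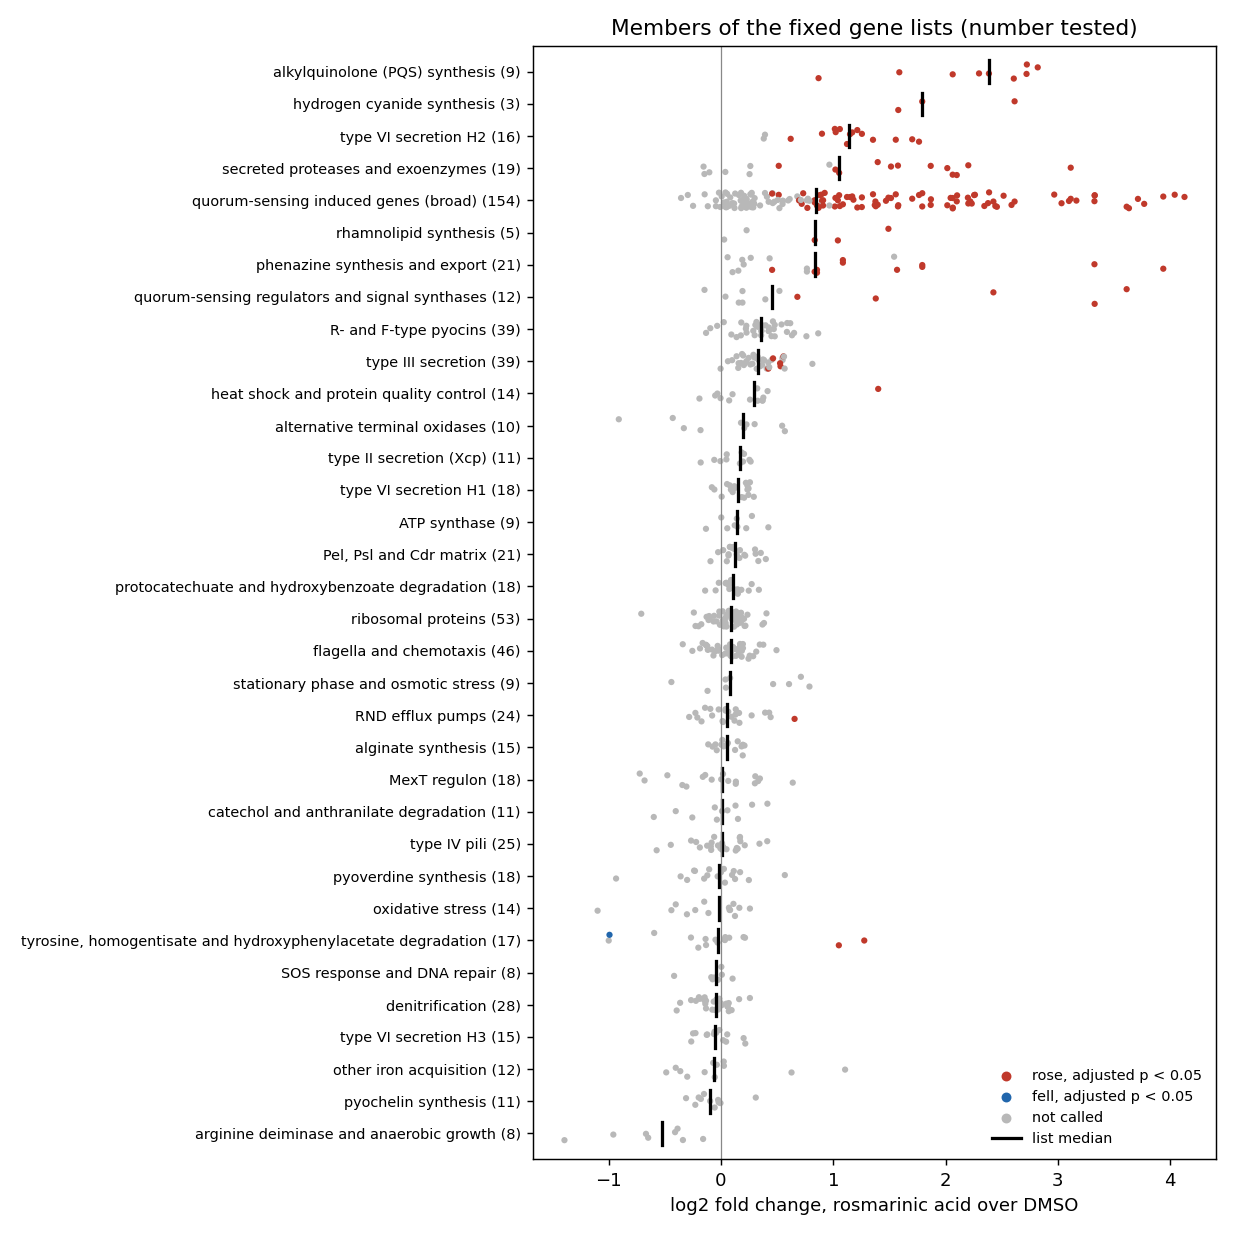
Log2 fold change, rosmarinic acid over DMSO, of the members of 34 gene lists, with the number tested in parentheses, a point per gene (red rose, blue fell, grey not called by edgeR) and a black bar at each list's median. Medians run from -0.53 for the arginine deiminase and anaerobic growth list to 2.39 for alkylquinolone synthesis.

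The authors' deposited table of the same comparison held 280 genes, 199 risen and 81 fallen. It held 130 of the 131 genes that rose here and all 13 that fell, and all 280 had the same sign in both. The remaining gene, PA2433, named after its values were seen, was 1.42-fold higher here (log2 0.50, SE 0.10; edgeR, Benjamini-Hochberg adjusted p = 0.0403). The other genes of the deposited table, most of its 81 fallen genes among them, were not called here. Both comparisons used the same read numbers, so shared calls and signs are no independent evidence. In the authors' deposited table the highest log2 fold changes were 3.47 at ambD, 3.39 at PA3328 and 3.13 at PA3330, and the lowest were -0.77 at mmsA, -0.76 at fahA and -0.72 at csaA. The log2 fold changes of the authors' deposited table were a median of 0.886 times the log2 ratios of its own group means, and 71 of its genes rose 2-fold or more. DESeq2 with its older shrunken fold changes also gave 71 such genes here, against 87 in the main test. Whether the authors' fold changes were shrunken is not stated, so their size is not directly comparable with those given here.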

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

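The direction of all 144 calls held in each alternative in which the gene was tested, and the broad quorum-sensing list stayed called in all, with adjusted p between 3.59e-82 and 3.29e-53 when each library was left out in turn and 0.00524 with an estimated correlation. The DESeq2 fit with shrunken fold changes and the thinned counts were chosen after the results were seen. DESeq2 called 245 genes, 57 of them fallen, and 246 with 57 fallen with shrunken fold changes, so that 76.7% of calls were rises against 91.0%. These 245 included all 144. In the only simulated draw run with DESeq2, 14.7% of its calls were unchanged genes against 9.6% for edgeR. In that draw DESeq2 recovered 63% of the 1.5-fold changes against 42% for edgeR. The draw used edgeR's own estimates of spread. The rounded RPKM values plus 1 gave 92 genes (83 risen), plus 0.1 gave 85 (75 risen), and plus 5 gave 102 (90 risen), 55 of them changed 2-fold or more against 88, and they moved the median log2 fold change of all genes from 0.0055 to -0.09, -0.10 and -0.08. They gave the broad list a median of 0.70, 0.73 and 0.48 against 0.85. The estimated correlation left 4 of 14 lists, and fry called 10, without H1 type VI (adjusted p = 0.554) and anaerobic growth, pyocins and heat shock (each adjusted p = 0.193). Over all alternatives that kept every library, 16 list calls were lost, most but not all of them under these tests. For tyrosine, homogentisate and hydroxyphenylacetate breakdown, fry gave the direction opposite to camera (adjusted p = 0.554), as it did for pyochelin (adjusted p = 0.983) and type IV pili (adjusted p = 0.963), and neither test called these 3 lists. The cause of these differences was not tested, nor was that of the next. With each library left out in turn, 105 to 284 genes were called, 100 to 165 risen, 3 to 119 fallen and 80 to 139 changed 2-fold or more, with 13 to 16 lists. The H1 type VI list lost its call without rosmarinic acid replicate 1 or 2 or DMSO replicate 1 (adjusted p up to 0.498), and heat shock without replicate 1 of either group (up to 0.0535). Without rosmarinic acid replicate 3 there were 284 genes, of which 140 were among the 144, with 119 fallen, whereas fallen genes numbered 8 and 4 without rosmarinic acid replicates 1 and 2 and 5, 7 and 3 without DMSO replicates 1 to 3. The replicate number as a block gave 148 genes, 129 risen and 19 fallen, with 127 of them among the 144. Of the 13 genes that fell in the main test it kept 9. Same-numbered libraries' deviations correlated by only 0.08, 0.18 and 0.04. In no same-numbered pair was each library the other's best match in the opposite group. For named genes 727 values kept their side of the threshold, 50 lost it and 7 gained it over the other alternatives, and 290, 43 and 3 did so with a library left out. The fallen mmsB lost its call in 12 of 20 alternatives, popD in 10, pcrH in 9, ibpA and PA5440 in 8, mmsA in 7 and fahA and rhlB in 5. The calls of PA3328, ambD and PA3330 were lost in 1, the rounded RPKM plus 0.1. Scaling by other factors or by library size only gave 131 to 143 genes. Thinning each library to the smallest total gave 140 genes.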

Other observations

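The test of the phenazine operon copies, the test of neighbouring genes and the thinning of libraries were chosen only after the result they concern was seen, and the genes named in this part were chosen after their values were seen. Among the 131 risen genes, 25 lay outside all fixed lists. The 6 adjacent genes from PA0492 to PA0497 were the largest block of these, with PA0492 at 244 ± 54.9 CPM with rosmarinic acid and 114 ± 12.8 CPM with DMSO (mean ± SD, n = 3 each; 2.15-fold) and PA0496 at 355 ± 61.8 and 184 ± 16.98 CPM (1.93-fold). PA0572 rose 2.85-fold from 32.7 ± 0.746 to 93.0 ± 10.04 CPM, PA0161 rose 1.94-fold, and PA2747 rose 1.55-fold from 162 ± 10.7 to 250 ± 25.7 CPM. The glycerol facilitator gene glpF rose 1.497-fold, pheC 1.49-fold and the nucleoside hydrolase gene nuh 1.39-fold.

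A block of genes was far lower in rosmarinic acid replicates 1 and 2 than in the 4 other libraries. The arginine/ornithine antiporter gene arcD had 329 and 173 CPM in replicates 1 and 2 but 3789 CPM in replicate 3, against 5153, 2425 and 3695 CPM in the DMSO libraries. PA0200 had 789 and 609.6 CPM against 4969 CPM in replicate 3 and 3027, 3274 and 3763 CPM with DMSO, and PA4348 had 102 and 89.4 CPM against 473 CPM in replicate 3 and 696, 430 and 572 CPM with DMSO. Without replicate 3, edgeR called 51 genes as fallen 2-fold or more, of which 3 were called with all libraries, and in 39 of the 51 replicate 3 was at or above the lowest DMSO library. Of these 51, 6 were on any fixed list, among them arcD, hemN and the terminal oxidase gene ccoN2. The genes were picked by the fit without replicate 3, so their low values in replicates 1 and 2 are no independent evidence of a fall.

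Fewer genes fell than rose, and 1 explanation is that rosmarinic acid replicate 3 held a share of untreated RNA. Such a share would pull its risen genes toward DMSO as well. The median log2 ratio to DMSO of the genes risen 2-fold or more was 1.84, 1.89 and 1.97 in replicates 1 to 3. Replicate 3 was thus not lower than the others (the lower of the other medians minus its own, -0.137), which argues against a mixture for these genes. They were picked with replicate 3 included, which favours genes that rose in it as well. A hypothesis that stays open is that the cultures may have differed in oxygen supply or density at harvest, since the medians of the arginine deiminase and anaerobic growth list also ran from -0.45 to 0.46 over the DMSO libraries. No oxygen or density value per flask was used here.

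The rise of quorum-sensing induced genes was weighed against 3 technical or culture explanations. Unequal depth is argued against by the thinned libraries, in which 83 genes rose 2-fold or more against 87 before. The choice among scalings of the read numbers mattered little: the lowest median log2 fold change of the broad list over 3 others was 0.801 against 0.845. On log2 of the rounded RPKM plus 5, which shrinks the change of low genes, it was 0.48. The TMM factors lay between 0.968 and 1.047, so these scalings differed little from each other. A scaling cause beyond the choice among them was not tested. Denser or later-phase cultures with rosmarinic acid cannot be told apart from a direct effect. Ribosomal protein genes had a median log2 fold change of 0.0924 (SE 0.0305), where a later phase would lower it. Stationary phase genes had a median of 0.0814 with an SE of 0.175, too wide to decide. Of these 9 genes 7 lay above 0 and 4 rose adjusted over the list alone, with 0 called over all genes. Their log2 fold changes ran from -0.441 to 0.788. Both SE are over the genes of a list, not over flasks. They are too narrow where those genes vary together (estimated correlation 0.537 and 0.255). PA4738 and PA4739 of the stationary phase list were also on the broad quorum-sensing list. An action of rosmarinic acid through RhlR, which it binds per the literature, was not tested by these data, since no strain without rhlR was analysed here.

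Both phenazine operons had risen genes, and a candidate explanation for the rise of phzD2, phzE2 and phzF2 in the second is that reads were shared between the copies. The largest ratio between the counts of the copies of phzC to phzG in any library was 1.1, within the 10% that such sharing predicts, so the rise of phzD to phzF cannot be assigned to either operon from these counts. The test did not cover phzB2 of the second operon, which had counts of its own and rose 2.97-fold, from 3.14 ± 0.235 to 9.25 ± 1.97 CPM (n = 3 each), against 48.7 CPM for phzB1 with rosmarinic acid. Whether part of its reads came from phzB1 was not tested.

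Risen genes lay next to another risen gene in 101 of 131 cases, against a median of 6 and at most 22 in 10000 random sets of as many tested genes (one-sided permutation test, p = 1e-04, the smallest that these sets can give). The random sets place genes singly and take no account of operons. The test therefore cannot tell a feature of this treatment from shared transcription of neighbours. The repeated counts of phzD to phzF are among the 101. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, gave as many called genes, 144 against 0 in the highest other, and likewise 1 gave as many changed 2-fold or more, 88 against 0. Each of the other splits has libraries of both treatments on each side. A strong treatment effect then widens the spread within its groups and lowers its calls, so these splits are no reference without an effect. For lists 3 of the 10 splits reached the real 14, the highest other calling 15, and for the broad list the real camera p of 7.45e-78 was reached by 1 split, the real one, the smallest of the others being 7.88e-13.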
